A study of Homo sapiens with 16 samples.

How the data were processed

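Differentiated HepaRG cells were kept for 3 days in medium with 2% DMSO and treated with vehicle (1% BSA), 30 nM formoterol, 0.25 mM palmitic acid with 0.5 mM oleic acid, or both, with 4 libraries per group and 16 in all. Per the labels, poly-A RNA was reverse transcribed with random hexamers and fragments of 370 to 420 bp were selected. The labels call the libraries independent replicates; whether they came from separate cultures is not given in the sources used here. The deposited table holds gene counts that the authors made from aligned reads. The program that counted and the strandedness are not given in the sources used here. The submitters' processing notes name HISAT2 2.0.5, DESeq2 and the mouse build mm39, but all 58735 gene IDs are human, 0 are mouse, and all have the name and coordinates of GENCODE release 29 (GRCh38, Ensembl 94), so the counts were read as human; 19951 genes are protein-coding.

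Depth was 32.5 × 1e6 to 65.7 × 1e6 counts per library. Genes were filtered with edgeR's filterByExpr, which left 18121 genes and 99.94% of counts (at least 99.92% in a library). Counts were scaled with TMM factors and fitted by edgeR 4.0.16 quasi-likelihood tests with 4 group means over 16 libraries (12 residual and 8.93 prior degrees of freedom, common dispersion 0.0096). The 5 pairwise comparisons and the interaction, the combination minus fatty acids less formoterol minus control, were tested, with Benjamini-Hochberg adjustment over genes at 0.05. Log2 CPM used a prior count of 2. Gene groups were tested with camera of limma 3.58.1 on voom weights with a preset inter-gene correlation of 0.01, adjusted over the 28 lists within a comparison, for single genes also over the members of a list alone. R was 4.3.3, and tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

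Comparisons, lists, the rule for named genes and alternatives were set before the data were examined. Named genes are the 5 largest rises and 5 largest falls among protein-coding genes past the threshold with at least 2 CPM in the higher group and no overlap between the groups' libraries, for fatty acids or formoterol against control and for formoterol added to fatty acids. To these come up to 2 members per list with the smallest p among those past the threshold, and genes fixed in advance, among them PPARGC1A and NR4A1, always. The other comparisons name the 3 largest rises and falls, without the overlap condition for the interaction. This gave 125 genes, some of which are not reported here. Of the 125, 72 overlap another gene and 18 a gene with more than 10% of their counts. The lists hold 564 entries and 550 distinct genes, 498 of them measured: cAMP and CREB response, beta-adrenergic signalling, gluconeogenesis, glycogen metabolism, glycolysis, fatty acid oxidation and ketogenesis, PPAR-responsive genes, lipid droplet, triglyceride synthesis and lipoprotein secretion, fatty acid synthesis and desaturation, cholesterol synthesis, bile acid synthesis and transport, mitochondrially encoded respiratory chain, nuclear-encoded respiratory chain, mitochondrial biogenesis and dynamics, unfolded protein response, integrated stress response, NRF2 oxidative stress response, chemokines and NF-kB targets, acute phase proteins, drug metabolism, proliferation, and markers of hepatocytes, cholangiocytes, hepatic progenitors, stellate cells and fibroblasts, macrophages and leukocytes, and endothelial cells. The rule that a list call should also hold with an estimated correlation was added after values were seen.

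Alternatives were DESeq2 size factors or total counts only, no filter or at least 1 CPM in 4 libraries, DESeq2 1.42.0 in place of edgeR, the replicate number as a block, each library left out in turn, a change of at least 2-fold, protein-coding genes only, only the 2 groups compared, and for lists an estimated correlation or fry; an estimated correlation with combination replicate 2 left out was added after the values were seen. The fit was tested on simulated data with 200 changed genes, drawn from genes with a mean of at least 2 CPM. Of 1.5-fold changes 65.2% to 71.6% were found in the pairwise comparisons and 41.8% in the interaction, and 3.17% to 5.34% of calls were false. Sequencing reads were not used here.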

Results

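RNA of differentiated HepaRG cells was sequenced after 3 days of treatment. HepaRG is a human liver line that, once differentiated, grows as a mixture of hepatocyte-like and cholangiocyte-like cells. The 4 groups were vehicle control, 30 nM formoterol (a beta-adrenergic agonist used as a bronchodilator), fatty acids (0.25 mM palmitic acid with 0.5 mM oleic acid), and fatty acids plus formoterol, called the combination from here on. Each group had 4 libraries, described in the labels as independent replicates but not as separate cultures, so p-values measure only the spread between these samples. Total gene counts ranged from 32.5 × 1e6 to 65.7 × 1e6 per library. Control libraries held 33.3 × 1e6 to 34.9 × 1e6 counts, formoterol 32.8 × 1e6 to 65.7 × 1e6, fatty acids 32.5 × 1e6 to 39.2 × 1e6 and the combination 33.1 × 1e6 to 41.7 × 1e6. Between 22699 and 24311 genes had a count in a library, and 18121 genes entered the tests. Gene levels below are mean CPM (counts scaled to 1e6 per library) ± SD over the 4 libraries of a group, changes are log2 fold changes ± SE, and coordinates are those of GRCh38.

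On the first principal component, with 17.3% of the variance, the libraries with fatty acids lay between 10.3 and 47.6 and those without between −35.9 and −7.17. Combination replicate 2 stood apart from the other 3 combination libraries. Its mean over the hepatocyte marker list was −1.02 log2 units from the control mean, against 0.648 to 0.757 in the other 3. Drug metabolism genes stood at −1.42 against −0.139 to −0.0610, and acute phase genes at −0.438 against 0.616 to 0.724. Its proliferation genes stood at 1.58 against 1.02 to 1.18, and its stellate and fibroblast markers at 0.746 against −0.104 to 0.283. The numbers of changed genes in comparisons with the combination are therefore also given without this library, and so are values of some gene lists.

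**Figure D1:**
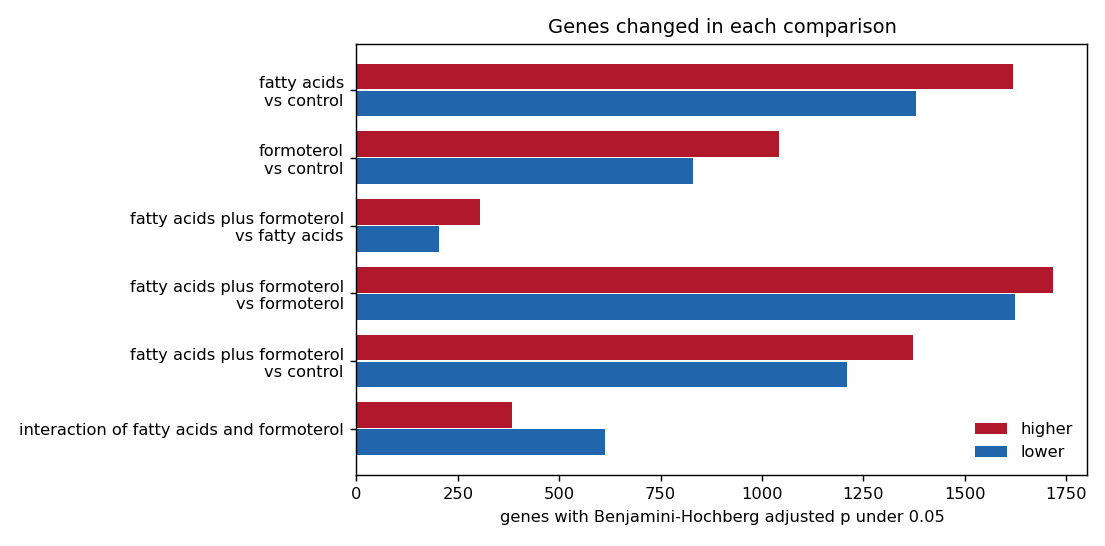
Bars show the number of genes higher (red) and lower (blue) in each comparison at an edgeR Benjamini-Hochberg adjusted p under 0.05, on a linear axis from 0. Fatty acids changed 2998 genes against control, formoterol 1872, and formoterol added to fatty acids 507.

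The first comparison asks what a load of palmitic and oleic acid changes in these cells. Of the genes that answer to the fatty acid receptors of the PPAR family 19 of 23 rose, while 12 of 22 genes of the cAMP response, 17 of 51 nuclear-encoded and 9 of 13 mitochondrially encoded respiratory chain genes fell. The last 3 list calls of camera are lost with an estimated correlation (adjusted p = 0.0540, 0.296 and 0.289). ANGPTL4 (ENSG00000167772, chromosome 19, 8363289 to 8374373), a secreted inhibitor of lipoprotein lipase, went from 5.67 ± 0.967 CPM in control to 38.5 ± 2.37 CPM with fatty acids (SD, n = 4). PDK4 (ENSG00000004799, chromosome 7, 95583499 to 95596491), the kinase that switches off pyruvate dehydrogenase, went from 739 ± 39.1 to 2480 ± 94.6 CPM. Both passed edgeR's quasi-likelihood test, with changes of 2.76 ± 0.14 (adjusted p = 1.14e-11) and 1.75 ± 0.07 (adjusted p = 8.65e-14). SDS (ENSG00000135094, chromosome 12, 113392445 to 113426301), the serine dehydratase that makes pyruvate from serine, had the deepest fall among the genes picked by size, from 34.4 ± 3.73 to 2.75 ± 0.433 CPM. Its change was −3.64 ± 0.15 (edgeR adjusted p = 3.28e-13), and it overlaps SDSL, whose counts were 0.565 times its own.

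Of the 18121 genes, 2998 changed at an edgeR adjusted p under 0.05, 1618 upward and 1380 downward, and 448 of these by at least 2-fold. In 2643 of the 2998 the 4 libraries of one group all lay above the 4 of the other. Over all tested genes 21.0% had no such overlap, where chance gives 2.90%. Other large rises were KRT16, an epithelial keratin, at 3.58 ± 0.34 (edgeR adjusted p = 2.24e-07), INHBE, the activin E subunit secreted by liver, at 3.29 ± 0.28, MS4A10 at 3.13 ± 0.58 and the apolipoprotein gene APOA4 at 2.49 ± 0.23. Large falls were those of MAPK4, an atypical MAP kinase, at −3.29 ± 0.24, the acyl-CoA thioesterase ACOT11 at −2.60 ± 0.35, TGM3 at −2.50 ± 0.43 and the interleukin receptor gene IL21R at −2.35 ± 0.25. ACOT11 overlaps FAM151A, whose counts were 3.83 times its own, and KRT16 has near-identical copies, so both levels are uncertain.

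Of the 23 measured members of the PPAR-responsive list 19 rose and 0 fell (19 and 1 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 2.40e-22). This call held with an estimated correlation (adjusted p = 0.0360). With all 16 libraries it is 1 of the 2 list calls in the 6 comparisons that did so, the other being the cAMP list after formoterol was added to fatty acids. With an estimated correlation and combination replicate 2 left out, chosen after the values were seen, 2 lists were called here, PPAR-responsive genes and cAMP (camera adjusted p = 0.000896 and 0.0179). TXNIP, an inhibitor of glucose uptake, rose 4.43-fold, and PLIN2, the main lipid droplet coat protein of hepatocytes, went from 248 ± 13.1 to 549 ± 10.3 CPM. Fatty acid oxidation and ketogenesis genes rose in 14 of 24 and fell in 1 (15 and 1 adjusted over the list alone; camera adjusted p = 9.57e-11, but adjusted p = 0.210 with an estimated correlation). Among them, CPT1A, which starts the entry of fatty acids into mitochondria, changed by 0.83 ± 0.06 and the thiolase ACAA2 by 0.89 ± 0.08. Cholesterol synthesis genes rose in 12 of 24 and fell in 1 (17 and 2 adjusted over the list alone) (camera adjusted p = 2.17e-06, but adjusted p = 0.311 with an estimated correlation). In the lipid droplet list 6 of 17 rose and 3 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.0728), and PLIN1, which overlaps the 3.35 times more counted PEX11A, changed by 1.42 ± 0.10. In the triglyceride and lipoprotein list 7 of 19 rose and 2 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.0539), with the phosphatidate phosphatase gene LPIN1 at −0.63 ± 0.05.

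cAMP and CREB response genes fell in 12 of 22 and rose in 2 (13 and 2 adjusted over the list alone), with a median of −0.48 (camera adjusted p = 4.44e-06, but adjusted p = 0.0540 with an estimated correlation). PPARGC1A (ENSG00000109819, chromosome 4, 23755041 to 23904089), a coactivator that drives mitochondrial genes, went from 104 ± 6.31 to 61.5 ± 5.59 CPM, a change of −0.76 ± 0.07 (edgeR adjusted p = 1.02e-07). NR4A1 (ENSG00000123358, chromosome 12, 52022832 to 52059507), an immediate cAMP target, stood at 3.72 ± 0.523 and 2.75 ± 0.506 CPM and did not pass (edgeR adjusted p = 0.149). The beta-adrenergic list as a whole had 2 of 23 members up and 3 down (the same counts adjusted over the list alone; camera adjusted p = 0.873).

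Nuclear-encoded respiratory chain genes fell in 17 of 51 and rose in 0 (30 and 0 adjusted over the list alone), with cytochrome c, CYCS, at −0.50 ± 0.06 and ATP5F1B at −0.40 ± 0.06 (camera adjusted p = 2.82e-10, but adjusted p = 0.296 with an estimated correlation). Mitochondrially encoded genes fell in 9 of 13 (10 adjusted over the list alone, camera adjusted p = 7.48e-07, but adjusted p = 0.289 with an estimated correlation). All genes of the mitochondrial chromosome together, not only these 13, held 5.76 ± 0.45% of counts against 6.91 ± 0.47% in control. Mitochondrial biogenesis genes fell in 3 of 23, also adjusted over the list alone (camera adjusted p = 0.00573, but adjusted p = 0.157 with an estimated correlation), among them the nuclear receptor ESRRA at −0.72 ± 0.08, which overlaps TRMT112 with 0.404 times its counts. Glycolysis genes fell in 6 of 19 and rose in 1 (9 and 3 adjusted over the list alone), with HK2, the hexokinase of growing cells, at −1.10 ± 0.10 and PKM at −0.48 ± 0.06 (camera adjusted p = 0.000486, but adjusted p = 0.20 with an estimated correlation). Gluconeogenesis genes went both ways, 6 of 14 up and 6 down (6 and 8 adjusted over the list alone; camera adjusted p = 0.0716), and the transaminase gene GOT1 changed by −0.86 ± 0.07. Glycogen genes had 2 of 15 up and 5 down (the same adjusted over the list alone; camera adjusted p = 0.0909), and fatty acid synthesis genes had 0 of 16 up and 3 down (the same adjusted over the list alone; camera adjusted p = 0.0728), with the synthase gene FASN at −0.40 ± 0.10.

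Proliferation genes rose in 16 of 20 (17 adjusted over the list alone), with the ribonucleotide reductase gene RRM2 at 1.12 ± 0.13 and the topoisomerase gene TOP2A at 1.04 ± 0.15 (camera adjusted p = 1.47e-09, but adjusted p = 0.20 with an estimated correlation). Hepatocyte markers rose in 9 of 20 and fell in 1 (15 and 2 adjusted over the list alone; camera adjusted p = 2.06e-05, but adjusted p = 0.407 with an estimated correlation), and ASGR1, an asialoglycoprotein receptor subunit, changed by 1.32 ± 0.21. Cholangiocyte markers rose in 6 of 12 and fell in 1 (8 and 1 adjusted over the list alone), with the keratin KRT19 at 1.52 ± 0.08 and CD24 at 1.40 ± 0.13 (camera adjusted p = 0.00145, but adjusted p = 0.103 with an estimated correlation). Progenitor markers rose in 2 of 7, also adjusted over the list alone (camera adjusted p = 0.0265, but adjusted p = 0.196 with an estimated correlation). That call was lost without control replicate 3 (camera adjusted p = 0.0667). Chemokine and NF-kB genes rose in 5 of 18 (7 adjusted over the list alone), with lipocalin 2, LCN2, at 1.28 ± 0.16 (camera adjusted p = 0.00063, but adjusted p = 0.0806 with an estimated correlation). Acute phase genes rose in 5 of 19 (6 adjusted over the list alone; camera adjusted p = 0.00227, but adjusted p = 0.492 with an estimated correlation). Drug metabolism genes rose in 5 of 23, also adjusted over the list alone (camera adjusted p = 0.0051, but adjusted p = 0.512 with an estimated correlation).

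Camera passed none of the bile acid, unfolded protein response, integrated stress, NRF2, stellate, macrophage and endothelial lists (adjusted p = 0.0870, 0.0728, 0.111, 0.389, 0.742, 0.742 and 0.0728 in that order). Members up and down were 6 and 0 of 16, 6 and 1 of 19, 2 and 4 of 18, 5 and 3 of 17, 3 and 2 of 14, 0 and 0 of 4, and 1 and 0 of 2. Adjusted over the list alone they were 7 and 0, 7 and 2, 3 and 5, 6 and 4, 5 and 2, 0 and 0, and 2 and 0. With combination replicate 2 left out of the shared fit, the triglyceride, lipid droplet, bile acid, unfolded protein response and endothelial lists passed too (camera adjusted p = 0.000325, 0.0377, 0.0152, 0.0258 and 0.0267, but adjusted p = 0.0982, 0.0859, 0.249, 0.194 and 0.0859 with an estimated correlation). In the same fit 3587 genes changed. Risen members were then 16 of the hepatocyte, 10 of the acute phase and 10 of the drug metabolism list, and fallen ones 29 of the nuclear-encoded respiratory chain. Members up and down were 3 and 8 for glycolysis, 2 and 5 for fatty acid synthesis and 2 and 0 for endothelial markers. Leaving out 1 control or fatty acid library also brought single lists of those near the threshold past it, with the lowest camera adjusted p, 0.0158, for gluconeogenesis without control replicate 3.

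**Figure D2:**
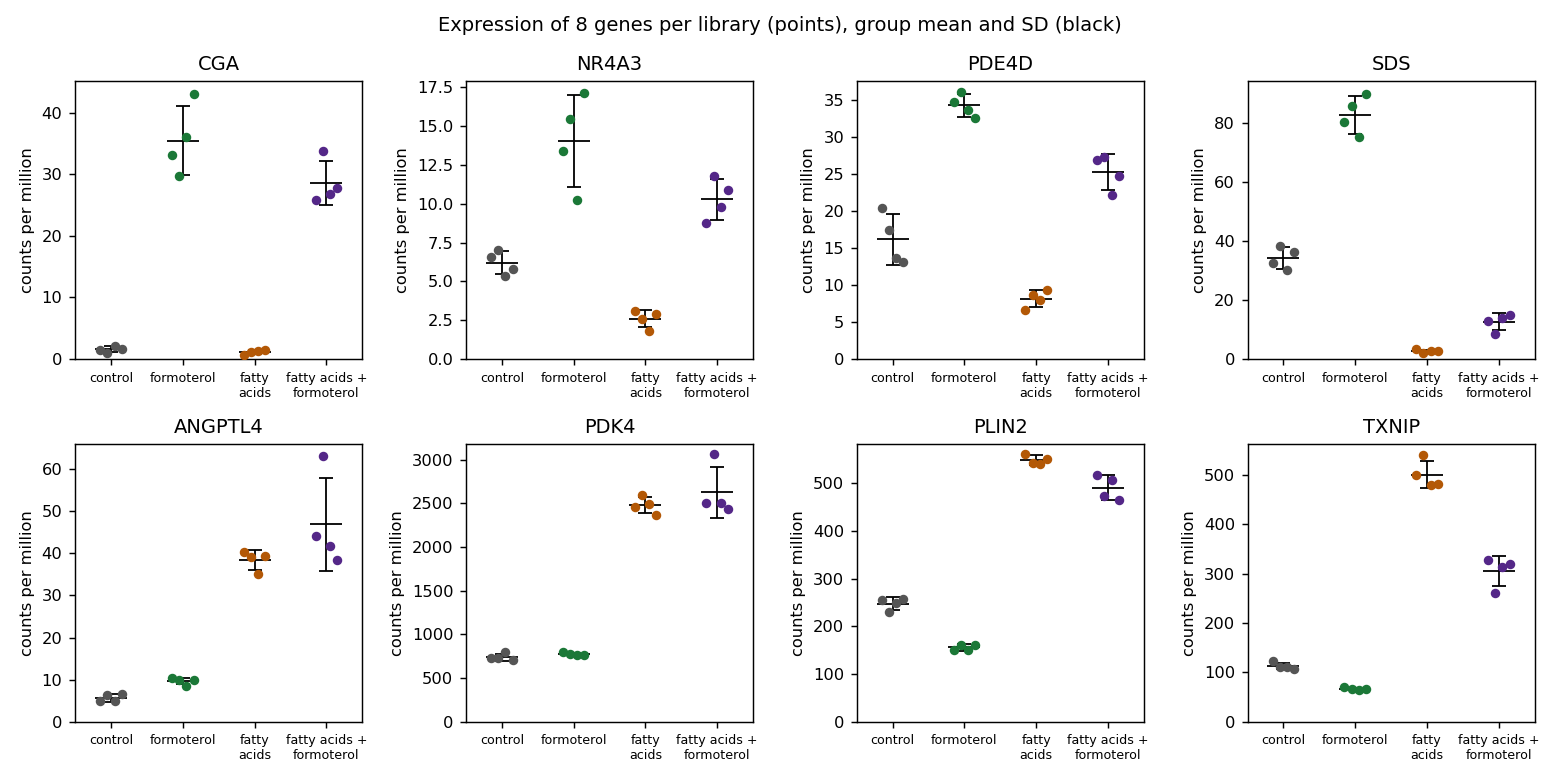
Points show CPM of 8 genes in each library by group, and black marks show the group mean and SD (n = 4). CGA lay between 25.8 and 43 CPM in the libraries with formoterol and at most at 2.16 in those without, and PDK4 lay at 2371 CPM or above in the libraries with fatty acids.

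The second comparison asks what formoterol changes in cells given no fatty acids. CGA (ENSG00000135346, chromosome 6, 87085498 to 87095406), the alpha subunit shared by the glycoprotein hormones and a classical target of cAMP, rose from 1.56 ± 0.489 to 35.5 ± 5.65 CPM (SD, n = 4), a change of 4.50 ± 0.20 (edgeR adjusted p = 9.28e-12). CPS1 (ENSG00000021826, chromosome 2, 210477682 to 210679107), the first enzyme of the urea cycle, rose from 49.3 ± 2.16 to 136 ± 11.0 CPM (edgeR adjusted p = 3.09e-11), and SDS from 34.4 ± 3.73 to 82.9 ± 6.35 CPM. Of the genes of glucose output 9 of 14 rose, of the unfolded protein response 12 of 19 and of the hepatocyte markers 15 of 20. These 3 list calls of camera are lost with an estimated correlation (adjusted p = 0.199, 0.185 and 0.207). The lipid droplet proteins PLIN1 and PLIN2 changed by −1.01 ± 0.10 and −0.67 ± 0.06.

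At an edgeR adjusted p under 0.05, 1872 genes changed, 1043 upward and 829 downward, 221 of them by at least 2-fold. In 1717 of these the 2 groups did not overlap, and over all tested genes 16.7% had no overlap against 2.90% by chance. Further rises were AGR2, a disulfide isomerase of secretory cells, at 2.30 ± 0.41, the apolipoprotein gene APOA2 at 2.15 ± 0.39 and the phosphodiesterase gene ENPP6 at 1.61 ± 0.22. Falls were those of IL21R at −1.85 ± 0.25, IGSF10 at −1.82 ± 0.37, the endothelial coreceptor gene ENG at −1.66 ± 0.34 and ZDHHC11 at −1.62 ± 0.28. U2AF1L5 changed by −2.96 ± 0.67, but its reads may be shared with near-identical copies. ZDHHC11 overlaps BRD9, whose counts were 7.88 times its own, and ENG an antisense gene with 1.03 times its counts.

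In the cAMP list 7 of 22 genes rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.00163, but adjusted p = 0.199 with an estimated correlation). The nuclear receptor NR4A3 (ENSG00000119508, chromosome 9, 99821855 to 99866891) went from 6.19 ± 0.741 to 14.0 ± 2.97 CPM and PDE4D, a phosphodiesterase that degrades cAMP, from 16.2 ± 3.43 to 34.3 ± 1.53 CPM. NR4A1 (0.16 ± 0.19, edgeR adjusted p = 0.666) and PPARGC1A (0.16 ± 0.07, edgeR adjusted p = 0.159) did not pass. In the beta-adrenergic list 3 of 23 rose and 3 fell, also adjusted over the list alone, with the alpha-1A adrenoceptor gene ADRA1A at −0.73 ± 0.10 (camera adjusted p = 0.428). Gluconeogenesis genes rose in 9 of 14 (13 adjusted over the list alone), with the glucose-6-phosphate transporter gene SLC37A4 at 0.53 ± 0.08 (camera adjusted p = 1.01e-11, but adjusted p = 0.199 with an estimated correlation). Unfolded protein response genes rose in 12 of 19 (14 adjusted over the list alone), with the transcription factor XBP1 at 0.65 ± 0.12 and calreticulin, CALR, at 0.44 ± 0.07 (camera adjusted p = 7.64e-13, but adjusted p = 0.185 with an estimated correlation). Hepatocyte markers rose in 15 of 20 (20 adjusted over the list alone), with HNF4A, a master regulator of hepatocyte genes, at 0.77 ± 0.13 (camera adjusted p = 1.81e-14, but adjusted p = 0.207 with an estimated correlation). Acute phase genes rose in 8 of 19 (9 adjusted over the list alone), with the fibrinogen chains FGB at 1.13 ± 0.14 and FGA at 0.83 ± 0.13 (camera adjusted p = 5.71e-06, but adjusted p = 0.321 with an estimated correlation).

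Fatty acid oxidation and ketogenesis genes rose in 8 of 24 (15 adjusted over the list alone) (camera adjusted p = 5.13e-08, but adjusted p = 0.280 with an estimated correlation). Cholesterol synthesis genes rose in 11 of 24 and fell in 0 (16 and 1 adjusted over the list alone; camera adjusted p = 9.31e-09, but adjusted p = 0.277 with an estimated correlation). Respiratory chain genes of the nucleus rose in 10 of 51 (17 adjusted over the list alone), with CYCS at 0.32 ± 0.06 (camera adjusted p = 1.01e-11, but adjusted p = 0.277 with an estimated correlation). No mitochondrially encoded gene of 13 passed, alone or over all genes, and the list call (camera adjusted p = 0.00603, but adjusted p = 0.466 with an estimated correlation) was lost without formoterol replicate 4 (camera adjusted p = 0.162); with combination replicate 2 left out of the shared fit 3 of the 13 rose. Bile acid genes rose in 6 of 16 (7 up and 1 down adjusted over the list alone), with the bile acid receptor gene NR1H4 at 0.81 ± 0.15 (camera adjusted p = 0.000805, but adjusted p = 0.321 with an estimated correlation). Drug metabolism genes rose in 5 of 23 and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.000653, but adjusted p = 0.377 with an estimated correlation), the fall being CYP1A1 at −1.37 ± 0.24. Stellate and fibroblast markers fell in 1 of 14 (4 adjusted over the list alone), the proteoglycan gene DCN at −0.62 ± 0.08 (camera adjusted p = 0.00338, but adjusted p = 0.277 with an estimated correlation). Of 2 measured endothelial markers 1 fell, also adjusted over the list alone, and that was KDR, a VEGF receptor, from 119 ± 7.36 to 44.2 ± 4.87 CPM (list camera adjusted p = 0.00603, but adjusted p = 0.185 with an estimated correlation). Camera also called the glycolysis, triglyceride, fatty acid synthesis, integrated stress and proliferation lists upward (adjusted p = 0.000193, 0.00603, 0.00621, 0.0027 and 0.00163, but adjusted p = 0.207, 0.377, 0.321, 0.217 and 0.379 with an estimated correlation). Members up and down were 7 and 1 of 19, 8 and 3 of 19, 6 and 2 of 16, 5 and 0 of 18, and 4 and 0 of 20 in that order. Adjusted over the list alone they were 10 and 1, 11 and 3, 10 and 2, 7 and 0, and 6 and 0. Camera did not pass the lipid droplet list (2 of 17 up and 4 down; 2 and 5 adjusted over the list alone; adjusted p = 0.0956) or the cholangiocyte list (2 of 12 up and 0 down; 2 and 1 adjusted over the list alone; adjusted p = 0.357). With combination replicate 2 left out of the shared fit, 13 drug metabolism, 15 fatty acid oxidation, 19 nuclear-encoded respiratory chain and 8 proliferation genes rose, and 4 stellate markers fell.

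With libraries scaled by total counts alone, 485 genes were higher and 1918 lower, against 1043 and 829 with TMM factors, and the median over all genes shifted by −0.135. Changes after formoterol alone are therefore relative to that median. With an estimated correlation no list was called, but with combination replicate 2 left out as well 7 were. These were the unfolded protein response, hepatocyte, acute phase, gluconeogenesis, cholesterol, endothelial and glycolysis lists (camera adjusted p = 0.00413, 0.0172, 0.0172, 0.0210, 0.0300, 0.0300 and 0.0367). The count of 1872 genes was 1002 without control replicate 3, 1118 without formoterol replicate 4 and 2588 without combination replicate 2.

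The third comparison asks what formoterol changes in cells already given fatty acids. CGA rose from 1.13 ± 0.377 to 28.5 ± 3.54 CPM (SD, n = 4), a change of 4.65 ± 0.21 (edgeR adjusted p = 9.69e-12). NR4A3 rose 3.97-fold and PDE4D 3.10-fold, and NR4A1 passed here, at 0.93 ± 0.20 (edgeR adjusted p = 0.00943). SDS rose from 2.75 ± 0.433 to 12.7 ± 2.83 CPM and MAPK4 (ENSG00000141639, chromosome 18, 50560078 to 50731824) from 0.984 ± 0.509 to 4.92 ± 0.876 CPM, both among the deepest falls after fatty acids. Proliferation genes rose in 13 of 20 and drug metabolism genes fell in 7 of 23, with list calls of camera that are lost with an estimated correlation (adjusted p = 0.110 and 0.208). CYP3A4 (ENSG00000160868, chromosome 7, 99756960 to 99784265), the main drug-oxidising cytochrome P450 of liver, dropped from 1917 ± 146 to 663 ± 306 CPM (edgeR adjusted p = 0.00112), with combination replicate 2 at 7.76 log2 CPM and the other 3 at 9.50 to 9.81.

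In all, 507 genes changed at an edgeR adjusted p under 0.05, 304 upward and 203 downward, 66 of them by at least 2-fold. In 470 of these the 2 groups did not overlap, and over all tested genes 9.30% had no overlap against 2.90% by chance. GZMB, the protease granzyme B, had a change of 3.84 ± 0.68 but spread widely in the combination (2.07 ± 1.70 CPM) and overlaps an antisense gene with 0.593 times its counts. CYP2A6 changed by −1.62 ± 0.28, the chemokine genes CCL16 by −1.41 ± 0.28 and CXCL13 by −1.26 ± 0.13, and KDR by −1.20 ± 0.15. CYP2A6 and CYP3A4 have close paralogs, so their levels are uncertain. Without combination replicate 2 their changes were −1.33 and −1.24. Without that library 590 genes changed, 330 up and 260 down (58 by at least 2-fold), and 406 of the 507 were among them. The count was 302 without fatty acids replicate 3 and 275 when only these 2 groups were fitted.

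cAMP and CREB response genes rose in 9 of 22 and fell in 1 (13 and 2 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 2.89e-12). This call held with an estimated correlation (adjusted p = 0.00459). Proliferation genes rose in 13 of 20 (16 up and 1 down adjusted over the list alone), with the mitotic kinase gene AURKA at 1.08 ± 0.12 and TOP2A at 0.78 ± 0.14 (camera adjusted p = 6.10e-18, but adjusted p = 0.110 with an estimated correlation). Leaving out combination replicate 2, whose proliferation score was the highest of its group, 9 rose and the median went from 0.65 to 0.45 (camera adjusted p = 0.0241 with an estimated correlation). Drug metabolism genes fell in 7 of 23 (13 adjusted over the list alone), with a median of −0.49 (camera adjusted p = 2.86e-13, but adjusted p = 0.208 with an estimated correlation). Without that library, whose drug metabolism score was the lowest, 7 fell with a median of −0.31 (camera adjusted p = 0.110 with an estimated correlation). Cholesterol synthesis genes fell in 3 of 24 (12 adjusted over the list alone; camera adjusted p = 3.77e-09, but adjusted p = 0.461 with an estimated correlation), and in 1 without that library. Fatty acid oxidation genes fell in 0 of 24 (7 adjusted over the list alone), with a median of −0.12 (camera adjusted p = 8.07e-05, but adjusted p = 0.461 with an estimated correlation). When combination replicate 2, the lowest library here as well, was left out, 1 fell and the median was −0.07 (camera adjusted p = 0.0443, and adjusted p = 0.479 with an estimated correlation).

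Hepatocyte markers had a median of −0.37, with 1 of 20 up and 0 down, also adjusted over the list alone (camera adjusted p = 0.00058, but adjusted p = 0.521 with an estimated correlation). The member that rose was CPS1, at 0.79 ± 0.07, and without combination replicate 2 the list had 2 up, 0 down and a median of −0.10 (camera adjusted p = 0.768). Camera also called the PPAR-responsive, triglyceride, bile acid and NRF2 lists downward (adjusted p = 0.00755, 0.000288, 4.84e-05 and 0.0250, but adjusted p = 0.461 with an estimated correlation in each). Without that library these were not called (camera adjusted p = 0.405, 0.0954, 0.0691 and 0.147), and NRF2 was also not called without fatty acids replicate 1 (camera adjusted p = 0.142). Members up and down were 1 and 1 of 23, 0 and 1 of 19, 0 and 1 of 16, and 0 and 3 of 17 in that order. Adjusted over the list alone they were 1 and 5, 0 and 1, 0 and 3, and 1 and 4, and without combination replicate 2 they were 2 and 1, 0 and 1, 0 and 2, and 0 and 3. TXNIP fell within the first of these, at −0.71 ± 0.07, the bile acid conjugating enzyme BAAT at −0.63 ± 0.12 and the aldo-keto reductase gene AKR1B10 at −0.48 ± 0.08. Upward calls of camera were unfolded protein response, nuclear-encoded respiratory chain and glycolysis, and endothelial markers were called downward (adjusted p = 0.000814, 0.00972, 0.0342 and 0.008, but adjusted p = 0.461, 0.690, 0.461 and 0.110 with an estimated correlation). Members up and down were 1 and 0 of 19, 0 and 0 of 51, 1 and 1 of 19, and 0 and 1 of 2 (2 and 0, 0 and 0, 6 and 2, and 0 and 1 adjusted over the list alone). With combination replicate 2 left out they were 7 and 0, 2 and 0, 4 and 1, and 0 and 1, and the unfolded protein response and endothelial calls then held with an estimated correlation (camera adjusted p = 0.00865 and 0.0241). The first 3 calls were lost without combination replicate 3 (camera adjusted p = 0.0527, 0.259 and 0.123), nuclear-encoded respiratory chain also without combination replicate 4 (camera adjusted p = 0.343), and glycolysis also without fatty acids replicate 4 or combination replicate 1 or 4 (camera adjusted p = 0.0552, 0.124 and 0.131).

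Acute phase genes had a median of 0.12, with 1 of 19 up (4 up and 1 down adjusted over the list alone; camera adjusted p = 0.803). When combination replicate 2, lowest in this list too, was left out, 8 rose and the list passed (median 0.35, camera adjusted p = 1.77e-11, and adjusted p = 0.0241 with an estimated correlation). Gluconeogenesis, mitochondrially encoded respiratory chain and integrated stress lists then passed upward too (camera adjusted p = 0.00255, 0.00232 and 0.0299, against 0.631, 0.886 and 0.136 with all libraries). They did not hold with an estimated correlation (camera adjusted p = 0.371, 0.479 and 0.228).

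**Figure D3:**
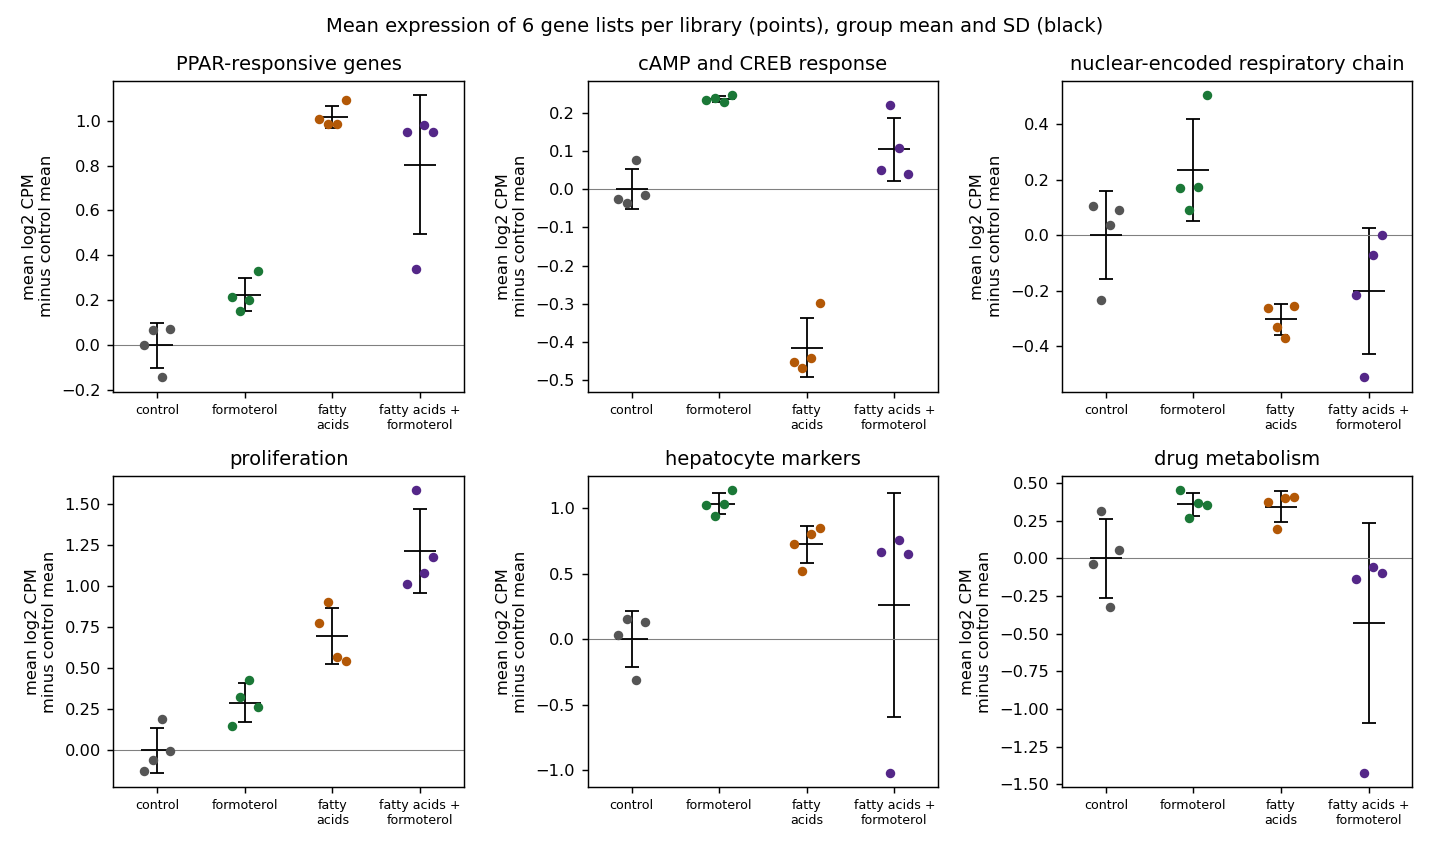
Points show, for 6 gene lists, the mean log2 CPM of each library minus the control mean, by group, with the group mean and SD in black (n = 4). In the combination group 1 library lies at −1.02 in the hepatocyte list, and the other 3 lie between 0.648 and 0.757.

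The interaction asks whether formoterol acts differently in the presence of fatty acids. It passed edgeR's test in 997 genes, 384 with a change that was more upward with fatty acids and 613 more downward. CYP7A1 (ENSG00000167910, chromosome 8, 58490178 to 58500236), the rate-limiting enzyme of bile acid synthesis, stood at 8.19 ± 4.00 CPM in control and 22.6 ± 3.14 with formoterol, but at 16.5 ± 2.25 with fatty acids and 7.33 ± 3.61 in the combination (SD, n = 4). Its interaction was −2.63 ± 0.45 (edgeR adjusted p = 0.0023). APOA2 followed at −2.42 ± 0.54 (edgeR adjusted p = 0.0127) and CCL16 at −2.36 ± 0.39 (edgeR adjusted p = 0.00189) and CCR7, a chemokine receptor gene, had one of 1.96 ± 0.41 (edgeR adjusted p = 0.00867). PPARGC1A (0.05 ± 0.10) and NR4A1 (0.77 ± 0.28) did not pass (edgeR adjusted p = 0.851 and 0.110). NR4A1 passed without combination replicate 4 (edgeR adjusted p = 0.0389).

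Hepatocyte markers had a more downward change with fatty acids in 14 of 20 members (20 adjusted over the list alone), with a median of −1.37 (camera adjusted p = 1.72e-17, but adjusted p = 0.213 with an estimated correlation). Drug metabolism followed in 12 of 23 (16 adjusted over the list alone; median −1.02; camera adjusted p = 2.40e-13, but adjusted p = 0.213 with an estimated correlation). The same direction was found in cholesterol synthesis in 13 of 24 (17 adjusted over the list alone; camera adjusted p = 8.99e-16, but adjusted p = 0.213 with an estimated correlation). Fatty acid oxidation genes did so in 10 of 24 (18 adjusted over the list alone; camera adjusted p = 4.08e-11, but adjusted p = 0.311 with an estimated correlation). Combination replicate 2 was the lowest of its group in the first pair of lists, and without it 19 hepatocyte and 15 drug metabolism genes passed, with medians of −1.08 and −0.77. Without it 12 cholesterol synthesis and 10 fatty acid oxidation genes passed, and the hepatocyte, drug metabolism and cholesterol calls held with an estimated correlation (camera adjusted p = 0.0243, 0.0344 and 0.0243). cAMP genes were more upward with fatty acids in 4 of 22 and more downward in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000887, but adjusted p = 0.213 with an estimated correlation), and in 3 and 1 without that library.

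Across genes, which are not independent replicates, the formoterol changes without and with fatty acids had a Pearson correlation of −0.00 and a Spearman correlation of −0.02. Calls nonetheless overlapped: 91 genes rose in both and 79 fell in both, where independent lists would share 17.5 and 9.29, and 29 went opposite ways, where 25.6 would. Without combination replicate 2 the correlations were 0.09 and 0.10, with 150 genes up in both, 115 down in both and 38 opposite, where independent lists would give 26.4, 15.5 and 40.5. With total counts alone the interaction split was 1030 up and 351 down, against 384 and 613, with a shift of 0.168 in the median of all genes. The interaction count was 444 without control replicate 3, 585 without formoterol replicate 4, 604 without fatty acids replicate 1, 640 without control replicate 4 and 653 without fatty acids replicate 3. It was 1026 without combination replicate 2, with 869 of the 997 genes among them.

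The design also asks whether formoterol moves genes against their change with fatty acids. Opposite calls do not by themselves show an altered fatty acid effect. A formoterol effect that is the same without fatty acids also gives them, and only the interaction asks whether the effects differ. Of the genes changed by fatty acids, 244 changed in the opposite direction when formoterol was added, 140 down and then up and 104 up and then down. SDS, MAPK4 and CHAC1, a glutathione-degrading stress gene, were raised by formoterol in the presence of fatty acids, CHAC1 from 5.67 ± 1.02 to 13.5 ± 1.41 CPM (SD, n = 4). TXNIP went from 500 ± 27.6 to 305 ± 30.2 CPM, against 113 ± 6.89 in control, and KRT19 from 168 ± 11.5 to 126 ± 10.2, against 58.7 ± 6.40. TXNIP also fell without fatty acids, to between 63.9 and 70.2 CPM in the libraries with formoterol alone, while SDS and MAPK4 passed the interaction test. Independent lists would give 41.3 opposite genes, and 78 changed the same way both times, where independent lists would give 42.6. Both comparisons use the fatty acid libraries, so unchanged groups were simulated against them 10 times. They gave a mean correlation of −0.498 against −0.42 observed and a mean covariance of −0.0520 against −0.0872 observed. With the fatty acid libraries split between the comparisons, 82 to 100 genes went opposite ways, where independent lists would give 8.63 to 12.5. In these splits 9 to 49 genes went the same way. The count was 294 without combination replicate 2 and 154 without fatty acids replicate 3.

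The last pair of comparisons asks what fatty acids change on top of formoterol and what both do together. Against formoterol alone, the combination changed 3342 genes at an edgeR adjusted p under 0.05, 1717 upward and 1625 downward, 547 of them by at least 2-fold. In 2755 the groups did not overlap (21.1% of all tested genes against 2.90% by chance). KRT16 rose by 3.53 ± 0.35, KRT15 by 3.17 ± 0.36 and the placental phosphatase gene ALPP by 2.71 ± 0.28. SDS changed by −2.71 ± 0.13, the tyrosine aminotransferase gene TAT by −2.67 ± 0.32 and UGT2B10, which has close paralogs, by −2.51 ± 0.26. PPARGC1A fell here as well (−0.72 ± 0.07, edgeR adjusted p = 4.24e-07). Nuclear-encoded respiratory chain genes fell in 34 of 51 (40 adjusted over the list alone; camera adjusted p = 7.73e-20, but adjusted p = 0.117 with an estimated correlation), and in 27 without combination replicate 2. Mitochondrially encoded genes fell in 11 of 13, also adjusted over the list alone (camera adjusted p = 4.50e-10, but adjusted p = 0.133 with an estimated correlation). Gluconeogenesis genes fell in 10 of 14 (11 adjusted over the list alone; camera adjusted p = 5.34e-11, but adjusted p = 0.117 with an estimated correlation), and glycolysis genes in 11 of 19 (12 adjusted over the list alone; camera adjusted p = 2.47e-07, but adjusted p = 0.0672 with an estimated correlation). PPAR-responsive genes rose in 12 of 23 (14 adjusted over the list alone; camera adjusted p = 9.95e-12, but adjusted p = 0.0672 with an estimated correlation). Without combination replicate 2, 16 PPAR-responsive genes rose, 8 gluconeogenesis genes fell and 1 rose, and 11 glycolysis and 11 mitochondrially encoded genes fell. The first 3 of these lists then held with an estimated correlation (camera adjusted p = 0.00158, 0.0353 and 0.0242), among 8 in all. Fatty acid changes without and with formoterol had a Pearson correlation of 0.28 and a Spearman correlation of 0.28 across genes, with 581 genes up in both and 633 down in both, where independent lists would share 153 and 124 (614 and 674 without combination replicate 2, where 141 and 120 would be shared). With total counts alone the split was 2965 up and 696 down, with a shift of 0.14 in the median of all genes. The count was 2700 without combination replicate 2, with 341 changed by at least 2-fold, and 2488 of these were shared.

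Against control, the combination changed 2583 genes at an edgeR adjusted p under 0.05, 1373 upward and 1210 downward, 461 of them by at least 2-fold. In 2090 the groups did not overlap (16.3% of all tested genes against 2.90% by chance). CGA rose by 4.19 ± 0.20 and KRT16 by 3.28 ± 0.34, while TGM3 changed by −2.88 ± 0.44 and DGCR6 by −2.87 ± 0.16. PRODH, proline dehydrogenase, changed by −3.15 ± 0.70, but it overlaps DGCR6 and spread widely in control (20.3 ± 15.0 CPM) and with fatty acids (20.4 ± 18.6 CPM). PPARGC1A (−0.56 ± 0.07, edgeR adjusted p = 6.01e-06) fell, and NR4A1 (0.49 ± 0.19, edgeR adjusted p = 0.0977) passed only without combination replicate 4 among the libraries left out (edgeR adjusted p = 0.0258). Proliferation genes rose in 18 of 20, also adjusted over the list alone, with a median of 1.54 (camera adjusted p = 6.04e-23, but adjusted p = 0.0636 with an estimated correlation), and 18 rose without combination replicate 2, with a median of 1.35 (camera adjusted p = 0.00699 with an estimated correlation). PPAR-responsive genes rose in 14 of 23 (16 adjusted over the list alone; camera adjusted p = 3.49e-19, but adjusted p = 0.0636 with an estimated correlation), and in 16 without that library (camera adjusted p = 0.000634 with an estimated correlation). Cholangiocyte markers rose in 6 of 12 and fell in 1 (7 and 2 adjusted over the list alone; camera adjusted p = 0.000837, but adjusted p = 0.0742 with an estimated correlation). Hepatocyte markers rose in 6 of 20 and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0247, but adjusted p = 0.662 with an estimated correlation). Without combination replicate 2, the lowest library of its group in this list, 16 rose and 1 fell (camera adjusted p = 2.35e-16, but adjusted p = 0.0505 with an estimated correlation). With all libraries kept but 1, the call was lost without control replicate 3 or combination replicate 1, 3 or 4 (camera adjusted p = 0.119, 0.137, 0.248 and 0.134). In all, camera called 16 lists in this comparison, 8 upward and 8 downward, and 0 with an estimated correlation. Among the downward ones were gluconeogenesis, glycogen and glycolysis (camera adjusted p = 0.0318, 0.0103 and 0.0318). These were not called without combination replicate 2 (camera adjusted p = 0.482, 0.0692 and 0.442). The gene count was 2811 without combination replicate 2, with 499 changed by at least 2-fold, and 2222 of the 2811 were shared.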

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

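The depth and cell-share tests of combination replicate 2, the tests of control replicate 3 and of the hepatocyte share in control, the scaling tests by comparison, and both tests of the opposite changes were chosen only after the result was seen; the tests by other splits of the libraries and of a wrong label were set before.

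In 58 of 612 groups of 4 libraries the highest or lowest library lay far from the other 3, with its gap to the nearest above Dixon's 95% limit as a share of the range of the group (the share is given in brackets). Chance flags about 1 in 20 groups, here 30.6. Combination replicate 2 accounts for 32 of these, 9 gene lists and 23 genes. It was the lowest of its group in the lists gluconeogenesis (0.830), fatty acid oxidation and ketogenesis (0.955), PPAR-responsive genes (0.950), triglyceride synthesis and lipoprotein secretion (0.862), cholesterol synthesis (0.866), bile acid synthesis and transport (0.853), acute phase proteins (0.907), drug metabolism (0.943) and hepatocyte markers (0.939). It was the lowest in APOA4 (0.896), AHSG (0.863), ASGR1 (0.923), ACAA2 (0.872), ABCB4 (0.956), AKR1B10 (0.851), BAAT (0.902), ESRRA (0.866), APOA2 (0.931), FGA (0.848), HNF4A (0.832), ABCB1 (0.857), XBP1 (0.871), EHHADH (0.891), CALR (0.840), GPI (0.868), CRP (0.951), CXCL13 (0.877), CYP3A4 (0.848) and DGCR6 (0.895), and the highest in PDK4 (0.870), TOP2A (0.83) and CCNB1 (0.864).

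In the other libraries the flags were few. Fatty acids replicate 4 was highest in the mitochondrial share of counts (0.935), cAMP and CREB response (0.845), mitochondrially encoded respiratory chain (0.897), integrated stress response (0.869) and MLXIPL (0.831) and lowest in TGM3 (0.855) and PLIN3 (0.889), and control replicate 3 was highest in endothelial markers (0.851) and KDR (0.950) and lowest in fatty acid oxidation and ketogenesis (0.901). Formoterol replicate 4 was highest in unfolded protein response (0.852) and lowest in GPAM (0.831), and control replicate 2 was lowest in integrated stress response (0.832). Fatty acids replicate 2 was lowest in drug metabolism (0.846) and ABCB4 (0.908), and formoterol replicate 2 was highest in MLXIPL (0.856) and lowest in hepatic progenitor markers (0.874) and THRSP (0.937). Fatty acids replicate 1 was highest in LBP (0.898) and NR1H4 (0.925), and control replicate 1 was lowest in NR4A1 (0.927) and ENPP6 (0.946). Combination replicate 1 was highest in ACACB (0.982) and lowest in PPARGC1A (0.860). Formoterol replicate 1 was highest in ENG (0.852), and fatty acids replicate 3 was lowest in GZMB (0.930).

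The interaction of fatty acids and formoterol passed its test for 42 named genes, where the formoterol effect differed between cells with and without fatty acids, and for 17 gene lists by camera with a preset correlation. On the log2 scale it was positive, more upward with fatty acids, for PLIN1 (0.658), PLIN2 (0.511), IL21R (1.79), MAPK4 (1.56), SDS (0.930), ACACB (0.379), ADRA1A (0.623), ZDHHC11 (1.86), ENG (1.73), PLIN4 (0.479), CRACR2B (2.04, but not called on leaving out 12 of the 16 libraries in turn, edgeR adjusted p = 0.0519 to 0.107) and CCR7 (1.96). It was negative for AHSG (−2.15), ASGR1 (−1.40), CITED2 (−0.405), ACAA2 (−0.446), CYP3A5 (−0.694), PPP1R3C (−0.751), SC5D (−0.701), AHR (−0.548), BAAT (−1.26), PEG10 (−0.978), APOA2 (−2.42), NQO1 (−2.30), ENPP6 (−2.27), CPS1 (−0.682), THRSP (−1.92), FGB (−0.767), NR1H4 (−0.868), ELF3 (−0.672), HNF4A (−0.759), ABCB1 (−0.827), EHHADH (−0.909), IDI1 (−0.840), SLC37A4 (−0.557), PFKFB3 (−0.393), CCL16 (−2.36), CYP3A4 (−1.65), CYP2A6 (−1.51), UGT2B10 (−1.61), TAT (−1.60) and CYP7A1 (−2.63). Levels are uncertain where a gene overlaps another with many counts, relative to its own 7.88 times in ZDHHC11, 3.35 in PLIN1, 1.18 in THRSP, 1.03 in ENG, 0.565 in SDS, 0.39 in SLC37A4, 0.20 in PLIN4, 0.142 in ABCB1 and 0.129 in AHSG. For lists the difference is less sure: 0 of the 17 held with an estimated correlation (3 did with combination replicate 2 left out too), and other splits of the libraries gave as many in 9 of 100. Without combination replicate 2 the list count was 12, with the glycogen, nuclear-encoded respiratory chain, NRF2, proliferation and stellate lists not called. The acute phase and unfolded protein response medians then stood at −0.26 and −0.12. With total counts only the median of all genes in the interaction was 0.168, so the sign of a small list median can turn with that shift. List medians were positive for cAMP and CREB response (0.277), proliferation (0.318) and stellate and fibroblast markers (0.316), and negative for gluconeogenesis (−0.546), glycogen metabolism (−0.0906, with a sign that turns with total counts only, 0.06), fatty acid oxidation and ketogenesis (−0.380), PPAR-responsive genes (−0.257), triglyceride synthesis and lipoprotein secretion (−0.545), fatty acid synthesis and desaturation (−0.264), cholesterol synthesis (−0.439), bile acid synthesis and transport (−0.861), nuclear-encoded respiratory chain (−0.129, also turning, 0.02), unfolded protein response (−0.180), NRF2 oxidative stress response (−0.160), acute phase proteins (−0.494), drug metabolism (−1.02) and hepatocyte markers (−1.37).

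Combination replicate 2 stands apart through lower hepatocyte, drug metabolism and acute phase genes and higher proliferation genes. Lower depth is argued against by its 33.1 × 1e6 counts, inside the 32.5 × 1e6 to 65.7 × 1e6 of the other libraries. A wrong label is argued against by treatment scores, 0 at the untreated and 1 at the treated mean. They were 0.628 for formoterol and 1.11 for fatty acids, where untreated libraries reached at most 0.142 and 0.0609. The formoterol score lies below the 0.909 to 1.11 of the other treated libraries. However, the score genes and the scale came from the other libraries, so part of that gap could come from this choice alone. A mixed sample was not tested. A lower share of hepatocyte-like cells would raise the cholangiocyte, progenitor and stellate markers alike only if the remaining cells carried them alike. Their gains differed by up to 0.818 log2 units against a summed spread of 0.272. Stellate markers gained 0.678 and cholangiocyte markers −0.140, with standard errors over members of 0.176 and 0.163. An equal gain is thus argued against, but a lower share with an unequal gain stays open. No biological explanation was tested, since the labels give none for a single library.

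Camera called hepatocyte markers higher than in control in each treated group, but not with an estimated correlation (adjusted p = 0.407 for fatty acids, 0.207 for formoterol and 0.662 for the combination, where 6 of 20 rose and replicate 2 lay below control, at −1.02). Control replicate 3 alone stays open for the combination, where the list median was 0.336 without it and 0.427 with all libraries (list scores of the combination libraries had an SD of 0.856), and the call ended (camera adjusted p = 0.119), as it did without combination replicate 1, 3 or 4. It is argued against for fatty acids (0.627, camera adjusted p = 0.000266) and formoterol (0.891, camera adjusted p = 2.06e-13). A lower share of hepatocyte-like cells in the control cultures would lower the cholangiocyte list in treated cells, if treatment left its genes alone. Its median was 0.552 with fatty acids and 0.784 in the combination. A rise of these genes within cells could hide a share difference, so this test cannot decide. With formoterol the cholangiocyte median was 0.0700 (camera adjusted p = 0.357), so a share difference cannot be told apart there either. It was −0.06 with total counts only, but the median of all genes then moved to −0.135 as well. The test of scaling for composition cannot decide, because subtracting the median of all genes removes most of what a change of scaling does. With total counts only the list lay above that median by 0.719 for fatty acids, 0.994 for formoterol and 0.395 for the combination. The standard errors of a member were 0.221, 0.220 and 0.220. The list medians themselves were then 0.705, 0.859 and 0.400, against 0.724, 0.991 and 0.427 with TMM factors.

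Of the genes changed by fatty acids, 244 changed the opposite way when formoterol was added. The fatty acid libraries that both comparisons share do not account for all of it. With them split, 82 to 100 opposite calls remained, at least 7.43 times those of independent lists, and 9 to 49 genes went the same way. Each comparison then had fewer libraries, so how much of the 244 comes from sharing cannot be told. Combination replicate 2 alone does not account for the count, with 294 opposite genes without it. Formoterol acting against part of the fatty acid response could then be a biological reading, offered as a hypothesis because it was found and tested on the same libraries. A formoterol effect that is the same without fatty acids would give such calls too, so their count does not show an altered fatty acid effect.

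Other splits of the libraries gave as many changed genes as the real one in 1 of 35 splits, the real one itself, for fatty acids against control (2998, highest other 0), formoterol against control (1872, 0), formoterol added to fatty acids (507, 14), the combination against formoterol (3342, 9) and against control (2583, 364). This share argues against chance for each of these 5 pairwise counts, but only weakly. The lowest share possible is 1 of 35, and it was not adjusted over the counts tested. Other splits mix libraries of both groups, so the treatment effect enters their spread and can lower their counts. The gap to the highest other split therefore adds no support. For the interaction the share was 2 of 100 (997, highest other 1192). Those splits shuffled all 16 libraries over the 4 groups, so the effects of each treatment entered their spread. They therefore cannot exclude chance for the interaction itself. For numbers of gene lists the real split alone reached its count only for formoterol against control (1 of 35, 19 lists, highest other 17). That margin is small, the share is again the lowest possible, and 0 of these 19 calls held with an estimated correlation. Chance is therefore not excluded there. It cannot be for fatty acids (3 of 35, 15, 16) or the combination against formoterol (6 of 35, 20, 21) either. Nor can it be for formoterol added to fatty acids (15 of 35, 14, 19), the combination against control (6 of 35, 16, 17) or the interaction (9 of 100, 17, 19). In the first pair every other split that reached the count had 2 or 6 libraries swapped and kept part of the real difference. For that pair the share cannot tell chance from a diluted effect. With 4 swapped, 0 to 5 and 6 to 17 lists were called.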

How the results depend on the processing

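Tests with an estimated correlation and combination replicate 2 left out together were chosen only after the result was seen, as was asking each list call to hold with an estimated correlation. None of 189 named-gene results reversed in 3275 settings. Most were picked for a large change or a small p, so a reversal was unlikely from the start. Calls were lost more often. With a library left out, 93 results lost their call, 3 gained one and 1488 stayed the same. A change of at least 2-fold lost 102, only the 2 groups compared lost 14, and total counts only lost 9. Counts of changed genes stayed within 1.5 times their value except as follows; the cause was not tested beyond what a setting does itself. A fold change of at least 2 left 448 (fatty acids against control), 221 (formoterol against control), 66 (formoterol added to fatty acids), 547 (combination against formoterol), 461 (combination against control) and 257 (interaction). Without a filter 880 genes changed when formoterol was added to fatty acids and 1523 in the interaction; with only the 2 groups 275, and with DESeq2 805, for formoterol added to fatty acids. With an estimated correlation 1, 0, 1, 0, 0 and 0 lists were called (2, 7, 5, 8, 4 and 3 with combination replicate 2 left out too, where drug metabolism for the combination against control had −0.101, camera adjusted p = 0.936), and with fry 3 for formoterol added to fatty acids and 8 for the interaction. Genes of at least 1 CPM gave a fatty acid-effect correlation of 0.398. Split fatty acid libraries left 93, 100, 82, 87, 87 and 89 opposite genes. Leaving out 1 library of the compared groups at a time gave 2276 to 2832, 1002 to 1613, 302 to 590, 2479 to 3351, 1975 to 2811 and 444 to 1325 genes (3587 and 2588 for the first pair without combination replicate 2, which shares their fit, with 20 and 19 lists), 15 to 17, 17 to 21, 12 to 15, 20 to 21, 14 to 16 and 12 to 19 lists, 154 to 294 opposite genes, and correlations of −0.0569 to 0.0876 (formoterol effect) and 0.242 to 0.307 (fatty acid effect). Without combination replicate 2, acute phase proteins reversed for the combination against formoterol (−0.08, camera adjusted p = 0.313, to 0.0819, camera adjusted p = 0.0269; all left-out libraries −0.274 to 0.0819), and drug metabolism for the combination against control (−0.21, camera adjusted p = 0.0318, to −0.101, camera adjusted p = 0.889, where the direction of the test turned; all left-out libraries −0.328 to −0.0624). With the replicate number as a block 3108, 1967, 537, 3447, 2583 and 1089 genes changed. Between groups, libraries of the same number correlated at 0.00956 on average and others at −0.00315, with group means removed. Of 16 libraries 7 correlated best with a library of their own number in another group. On average the number showed no clear pairing, but a weak one is not excluded. On simulated data 41.8% to 71.6% of changes of 1.5-fold and 80.6% to 97% of 2-fold changes were found. The changed genes were drawn from those with a mean of at least 2 CPM, and no simulated library stood apart. More may therefore be missed among lower genes, for which these shares set no bound.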

Other observations

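The amino acid breakdown and keratin lists, and all tests of them, were chosen only after the result was seen, when some members' values (GOT1 and CPS1) were already known. Single genes of amino acid breakdown fell with fatty acids and others rose with formoterol: AASS, of lysine breakdown, changed by −1.25 with fatty acids, the branched-chain transaminase gene BCAT2 by −0.92, ALDH6A1 by −0.83 and HGD, of tyrosine breakdown, by −0.70. With formoterol alone KYNU and ACMSD, of tryptophan breakdown, changed by 0.89 and 0.88, the glycine decarboxylase gene GLDC by 0.83 and HPD by 0.80. With fatty acids, keratin genes outside the fixed lists rose, KRT14 by 2.97, KRT6A by 1.91, and KRT8 and KRT18 by 0.62 each.

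The hypothesis that amino acid breakdown falls as a group with fatty acids and rises with formoterol was tested on 45 measured genes, without the 5 that prompted it (SDS, TAT, PRODH, ASPDH and CTH). With fatty acids 2 rose and 11 fell (median −0.10, camera p = 0.00108, but p = 0.394 with an estimated correlation), and with formoterol alone 18 rose and 1 fell (median 0.35, camera p = 4.34e-11, but p = 0.10 with an estimated correlation), so both may be correlated spread and stay open. The part that formoterol raises the group in the presence of fatty acids was negative: of 45 genes 4 rose and 0 fell, with a median of −0.08, or 0.00 without combination replicate 2 (camera p = 0.0503, downward, and p = 0.607 with an estimated correlation, both with all libraries). For the combination against formoterol 0 rose and 31 fell (median −0.46, camera p = 8.50e-23, p = 0.0210 with an estimated correlation). These values include combination replicate 2, and without it the median was −0.357. The p-values of this list are not adjusted. The list also holds GOT1 and GPT of the gluconeogenesis list and TDO2, ARG1 and CPS1 of the hepatocyte list, so it is not independent of those.

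The hypothesis that keratins rise as a group with fatty acids was tested on 11 genes, without KRT16 and KRT15, which prompted it. Whether the tested keratins share reads with those genes was not examined. KRT16 and KRT15 were named for the combination against formoterol, so that comparison is not an independent check. With fatty acids 6 rose and 0 fell (median 0.62, camera p = 0.000149, p = 0.0108 with an estimated correlation). For the combination against formoterol 5 rose and 0 fell (camera p = 0.000752, p = 0.0219 with an estimated correlation), while formoterol alone gave 1 up and 1 down (camera p = 0.579). Cholangiocyte markers, which include KRT19 (1.52 with fatty acids), rose as well, in 6 of 12 with fatty acids (median 0.55) and in 4 of 12 for the combination against formoterol (median 0.34), with list calls of camera lost with an estimated correlation (adjusted p = 0.103 and 0.126). A wider epithelial response to fatty acids could lie behind it, which these libraries cannot test.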
